A study of Homo sapiens with 16 samples.

How the data were processed

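NicE-seq libraries from 16 U87 samples were assigned to vehicle, belinostat, AsiDNA and combination groups by the treatment field of the labels, with 4 libraries per group whose titles number them 1 or 2 and D1 or D2. Per the labels' protocols, cells were fixed with formaldehyde, nuclei were labelled with the nicking enzyme Nt.CviPII, DNA polymerase I and biotinylated nucleotides, and biotin-labelled fragments were captured on streptavidin beads. Per the submitters' processing notes, Trim Galore 0.5.0, Bowtie2, SAMtools, Picard, MACS2 and deepTools were used with the hg38 build. The role, order and options of these tools, any control input or blacklist, and the way the 4 libraries of a group were combined are not given in the sources used here. The 4 libraries of a group name the same list in the labels, so 1 list stands for each group.

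Each peak carries values that the authors' peak caller gave it. The deposited fold enrichment is a ratio over local background, and the deposited p-value and q-value are on the −log10 scale. The lowest −log10 q in the files is 1.30, a q of 0.050. None of these values is scaled between lists. They were used to rank or filter peaks within a list, as percentiles of the fold enrichment. They were not compared as levels between lists, apart from the list medians given with the flagged results. No read counts were used, so depth per library is unknown and a longer list can reflect more reads as well as more open chromatin.

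Peaks on chromosomes 1 to 22 and X were kept. A peak was gained or lost in a pair of lists when no peak of the other list overlapped it by at least 1 bp. Peaks of all lists were merged into regions wherever they overlapped by at least 1 bp, and each region was assigned to 1 of 15 patterns by the lists that had a peak in it. The design called for a window around transcript starts. The gene table used (GRCh38.p14, the same build as the files) gives 1 start and end per gene without strand or exons, so a gene counted as having a peak when a peak came within 1000 bp of either end of the gene, for 19974 protein-coding genes. This replaces promoters throughout. The peak location by exon and intron and the motif search were left out because no genome sequence was used, and random gene lists were not matched on base composition for the same reason. Positions are 1-based.

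The comparisons were belinostat over vehicle, AsiDNA over vehicle, the combination over vehicle, over AsiDNA and over belinostat, and the presence patterns over all 4 lists. With 1 list per group these are descriptions. Shares have Wilson 95% intervals, ratios of counts have the same interval of the share turned into a ratio, and both cover counting error only. The overlap of comparisons that share no list was set against the product of their sizes over the number of regions. That number includes the regions held by every list, which cannot be gained or lost. Named genes were, per pattern, the 10 with the highest value of the lowest within-list percentile over the lists holding a peak, the 5 regions over 1000 bp from a gene end ranked the same way, and for each of 20 gene lists (422 genes, all matched) up to 4 members per pattern plus the 2 highest-ranked members open in every list. The gene lists, this rule, the groups and the settings to be varied were fixed before the data were examined. Counts of list members were placed among 10000 random lists of the same size.

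Added after the data were seen were the filter at percentile 50, the check of gene ends through merged regions, peak widths, local gene density in a 1 Mb window with intervals from 2000 resamples of 5 Mb blocks, and regions within 10 kb of listed genes, set against random lists matched on gene length. Settings varied as set out beforehand were a threshold of −log10 q of 5, lists of equal length, a margin between present and absent, 50% overlap, summits within 250 bp, windows of 500 and 2000 bp, and all sequences. The functions were tested on 159593 simulated regions of known pattern, of which 100% were recovered, and gene-end calls on chromosome 21 differed from a direct search at 0 of 239 genes. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.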

Results

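Chromatin accessibility was mapped in U87 cells, an established human glioblastoma line, by NicE-seq, in which a nicking enzyme and a DNA polymerase tag open chromatin with biotinylated nucleotides before capture and sequencing. The series asks whether AsiDNA and belinostat alter accessibility across the genome. AsiDNA is a short double-stranded DNA decoy that imitates a broken DNA end and occupies the repair machinery, and belinostat is a hydroxamate inhibitor of histone deacetylases. The 16 libraries fall into 4 groups of 4, namely vehicle, belinostat, AsiDNA and the combination of both drugs. Belinostat was given at 1 µM for 24 h. The labels give no AsiDNA dose, and their protocol text speaks of cells named MTU87 and LTAU87 where the sample fields say U87, so the way in which the AsiDNA groups were exposed is not settled here. Each group has 1 peak list, so no spread between replicates can be given for any value, no p-value was computed, and the intervals are Wilson 95% intervals that cover counting error only. Read depth per library is unknown.

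The 4 lists were of similar size. On chromosomes 1 to 22 and X they held 130318 peaks for vehicle, 138937 for belinostat, 138273 for AsiDNA and 134865 for the combination, covering 62.4, 66.1, 67.6 and 63.3 Mb of hg38. Median peak widths were 398, 408, 410 and 401 bp in the same order. Peak summits lay within 1000 bp of an end of a protein-coding gene in 10.6% of vehicle peaks (interval 10.4 to 10.7), 10.1% of belinostat peaks (9.94 to 10.3), 10.1% of AsiDNA peaks (9.93 to 10.2) and 10.2% of combination peaks (10.1 to 10.4). A further 43.3% to 43.8% lay in gene bodies. Merging the lists gave 183659 regions, of which 94332 (51.4%) held a peak of every list. Of 19974 protein-coding genes, 12806 had a gene-end peak in all 4 lists and 5476 in none.

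The belinostat and vehicle lists differed by more peaks than the AsiDNA and vehicle lists, in both directions. Against vehicle, 33268 belinostat peaks (23.9%, interval 23.7 to 24.2) had no vehicle counterpart, and 24751 vehicle peaks (19%, 18.8 to 19.2) had no belinostat counterpart. Within the AsiDNA groups, the combination list had 24809 peaks (18.4%, 18.2 to 18.6) that the AsiDNA list lacked, and 28879 AsiDNA peaks (20.9%, 20.7 to 21.1) were missing from the combination. Peaks found in 1 list of a pair were weak: gained belinostat peaks had a median fold enrichment at percentile 20.3 of their own list, while the belinostat peaks shared with vehicle were at percentile 60.9. Fold enrichment is the authors' value for each peak and, apart from the list medians given with the flagged results, is used only to rank peaks within a list.

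Because the belinostat comparisons with and without AsiDNA use different lists, regions that behaved alike in both are the most informative. Both belinostat lists, and neither of the others, held 11179 regions, while 9257 regions were held by both lists without belinostat and by neither belinostat list. Together these were 11.1% of all regions (interval 11 to 11.3). The gained set was 2.56 times, and the lost set 2.48 times, the number that independent comparisons of these sizes would share over all 183659 regions. Only 89327 regions were not in every list and could be gained or lost. Counting only these would make both ratios lower. A split of the lists that follows neither drug, the single drugs against vehicle and combination, gave 3904 regions (2.13%), so the belinostat split was 5.23 times as large (interval 5.06 to 5.42). Regions where belinostat acts in opposite directions without and with AsiDNA would also fall in that split, so it is not free of drug effects. Among regions at or above percentile 50 of each list that held them, a filter chosen after the data were seen, the belinostat split held 773 gained and 951 lost regions against 20 in the split of neither drug.

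**Figure D1:**
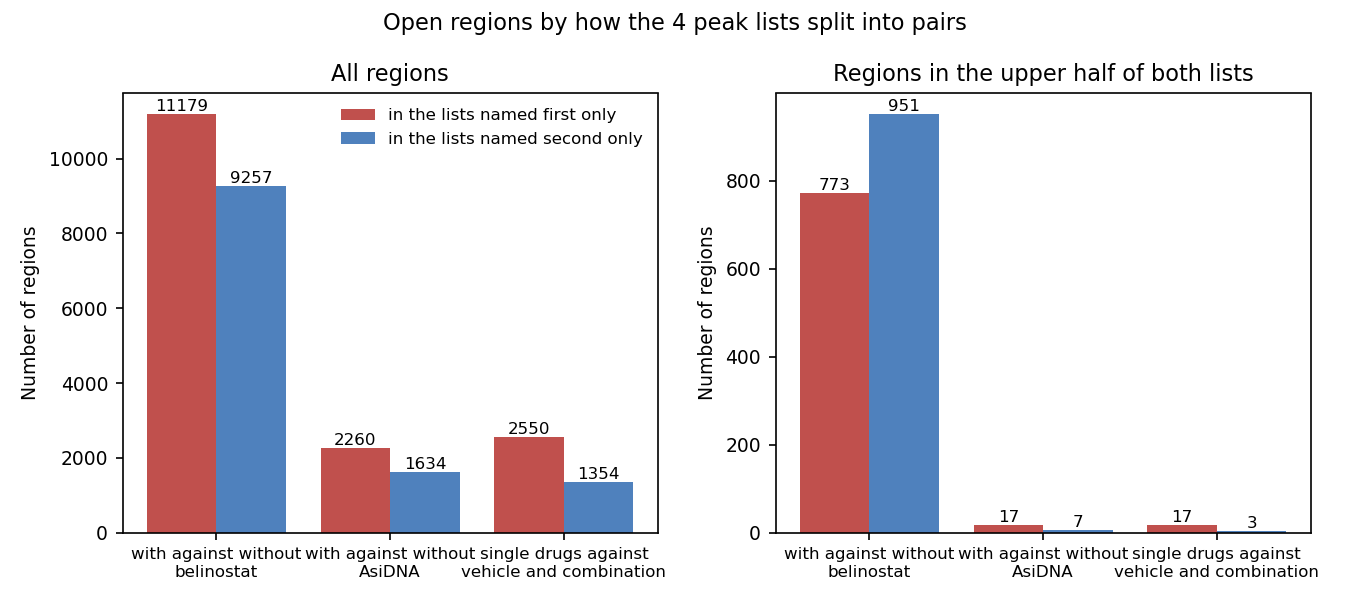
Number of merged open regions (vertical axis) present in exactly 1 pair of the 4 peak lists, for each of the 3 ways to split the lists into pairs; red bars are regions in the lists named first and blue bars those in the lists named second. The left panel shows all regions, with 11179 and 9257 in the belinostat split, and the right panel those at or above percentile 50 of both lists that held them, with 773 and 951.

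The strongest belinostat-only regions away from gene ends lay inside or between genes of diverse function. On chromosome 5, 134927005 to 134927215 in the body of PCBD2 carried fold enrichments of 23.4 with belinostat and 24.1 with the combination, and had no peak in the other lists. A region in the body of SPICE1, a centriole component, at 113496894 to 113497301 on chromosome 3 had folds of 14.9 and 14.2, and 1 in PAICS, an enzyme of purine synthesis, at 56448285 to 56448707 on chromosome 4 had 12.8 and 12.9. Others lay between genes on chromosome 17 (53106131 to 53106394) and chromosome 4 (36773455 to 36773853). The PCBD2 and chromosome 17 regions were 211 and 264 bp wide, against a median of 353 bp for belinostat-only regions. With no blacklist or control input known, high folds in such narrow regions were not checked further. Among regions that were present only without belinostat, the strongest was in PAPSS2, which makes the sulphate donor for sulphation, at 87670570 to 87671090 on chromosome 10, with folds of 12.8 in vehicle and 13.6 in AsiDNA. The next lay between genes 202 kb from IL7 on chromosome 8 (79007292 to 79007788, folds 12.5 and 15.4). Further ones lay in RSBN1L (14.4 and 12.1), in NCOR1, the corepressor that brings histone deacetylase complexes to target genes (16178868 to 16179209 on chromosome 17, folds 11.1 and 15.9), and in THADA (11.2 and 11.7).

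At gene ends, 176 genes had a peak in both belinostat lists only and 155 in both lists without belinostat only, against 80 genes in the split of neither drug, a ratio of 4.14 (interval 3.24 to 5.28). The ranking fixed in advance named 10 genes per direction, but a gene near the edge of a peak can change class when the peak border moves. For 7 of the 10 belinostat-only genes the whole merged region at the gene end also followed the pattern. These were ANGPTL7, an angiopoietin-like secreted protein (folds 10.2 with belinostat and 8.77 with the combination), ABCC2, an efflux transporter of organic anions (9.64 and 8.25, chromosome 10, 99852501 to 99852977), CIDEB and LTB4R2, neighbours that share a peak (6.95 and 7.85), KRT5, a basal epithelial keratin (6.72 and 6.93), ETDB (6.49 and 6.93) and BST2, an interferon-induced antiviral membrane protein (7.28 and 6.63, chromosome 19, 17406175 to 17406670). CIDEB and ETDB also kept the pattern with windows of 500 and 2000 bp, whereas ANGPTL7 and BST2 lost it at 500 bp, ABCC2 and LTB4R2 at 2000 bp and KRT5 at both. For KRTAP5-4, RBBP8 and LOC102724250 a list without belinostat had a peak in the same merged region. Applying the same ranking to genes whose merged regions followed the pattern, which was decided after the data were seen, added TBC1D28 (6.70 and 6.46), NPY4R, a neuropeptide receptor (6.19 and 7.34), APBB1IP (6.14 and 7.35), LNX1 (6.72 and 6.23) and ZNF556 (6.19 and 6.07), of which TBC1D28 lost the pattern at 500 bp and LNX1 at 2000 bp.

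Of the 10 genes named for an end open only without belinostat, UCP3, a mitochondrial carrier of skeletal muscle (folds 8.99 in vehicle and 8.41 in AsiDNA, chromosome 11, 74000689 to 74001166), LYPD6B (8.02 and 7.20) and CPA6, a carboxypeptidase (6.62 and 7.01), kept the pattern over the whole merged region, LYPD6B losing it at 500 bp. The other 7, ACMSD, SPMIP3, LOC124901867, PPM1N, IL24, LOC124903723 and KLHL15, did not, although ACMSD carried the highest folds of the set (13.9 and 15.3). The ranking by merged regions added TMEM171 and its neighbour LOC124901001 at a shared peak (6.39 and 7.63), IL36G, a cytokine of epithelia (5.44 and 6.07), CLDN15, a tight-junction claudin (5.44 and 6.31), SPTB, the erythrocyte beta-spectrin (5.32 and 6.73), and SCNN1G, a subunit of the epithelial sodium channel (5.98 and 5.31). TMEM171 lost the pattern with both other windows, and LOC124901001 and CLDN15 at 500 bp.

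Regions gained with belinostat lay closer to gene ends by median distance, and in more gene-dense sequence, than regions lost with it. Belinostat-only regions were a median of 26.1 kb from the nearest gene end and had on average 10.4 protein-coding genes in the surrounding 1 Mb, against 42.2 kb and 7.67 genes for regions present only without belinostat. The gap in distance was not particular to belinostat. In the split of neither drug the medians were 30.8 kb for single-drug regions and 49.1 kb for vehicle and combination regions. In the AsiDNA split they were 40.9 and 41.0 kb. Few regions of the belinostat split lay directly at gene ends: 3.61% (interval 3.28 to 3.97) of gained and 4.40% (4.00 to 4.83) of lost regions. Of the regions common to all lists 12.6% lay there. Gained and lost regions had similar shares in gene bodies (48.2% and 47.6%) and between genes (48.2% and 48.0%). By chromosome, gained regions outnumbered lost ones most on chromosome 19, the densest in genes, with 373 against 126 (ratio 2.96, interval 2.42 to 3.62), and the ratio was 1.88 on X, 1.73 on chromosome 22 and 1.65 on chromosome 20. It was 0.81 on chromosome 13 (interval 0.69 to 0.95), 0.87 on 18 and 0.88 on 4. In the split of neither drug the ratio was also high on chromosome 19 (2.65, interval 1.65 to 4.27) and on X (3.0). Over all chromosomes the ratio was 1.21 in the belinostat split and 1.88 in the split of neither drug. Over the 23 chromosomes, which are not independent replicates, the belinostat ratio rose with gene density (Spearman's rho 0.82, Pearson's r 0.88). X departed from this trend, ranking 16 in gene density (5.44 genes per Mb) but 2 in the ratio.

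The same lean was present in each belinostat comparison but was not confined to them. The ratio of mean local gene density, gained over lost regions, was 1.31 for belinostat over vehicle (interval 1.26 to 1.36, resampling 5 Mb blocks) and 1.19 for the combination over AsiDNA (1.16 to 1.22). For AsiDNA over vehicle the means were 8.68 and 8.24 genes per Mb (interval of the ratio 1.03 to 1.08), and for the combination over belinostat the ratio was 0.88 (0.85 to 0.90). In the split of neither drug, single-drug regions were 1.26 times as gene-dense as the vehicle and combination regions (1.17 to 1.38), though its ratios by chromosome followed gene density with a rho of 0.16 and an r of 0.39.

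**Figure D2:**
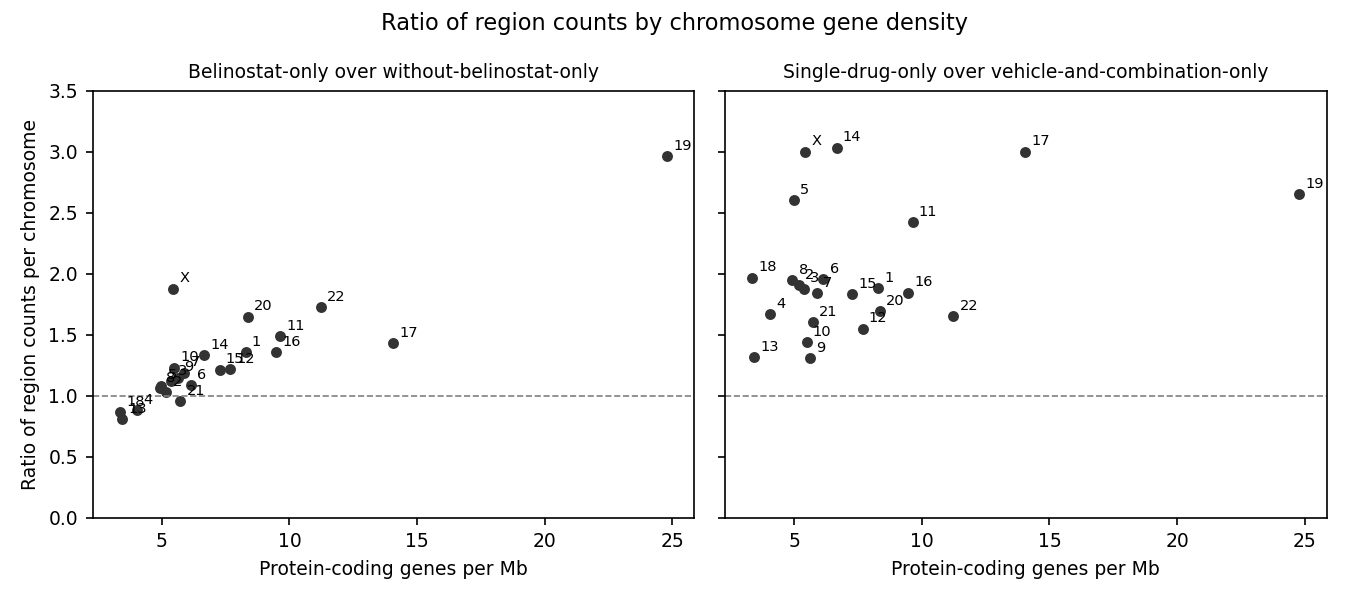
Ratio of region counts on each chromosome (vertical axis, no unit) against protein-coding genes per Mb (horizontal axis); each point is a labelled chromosome and the dashed line marks a ratio of 1. Left, belinostat-only over without-belinostat-only regions, highest on chromosome 19 at 2.96 and lowest on chromosome 13 at 0.81; right, the split that follows neither drug.

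The AsiDNA and vehicle lists differed less. Against vehicle, 24339 AsiDNA peaks (17.6%, interval 17.4 to 17.8) were gained and 15815 vehicle peaks (12.1%, 12 to 12.3) were lost. Against the belinostat list, the combination list gained 16880 peaks (12.5%, 12.3 to 12.7) and lost 21041 (15.1%, 15.0 to 15.3). In every pair, belinostat over vehicle included, gains minus losses follow the difference in length of the 2 lists almost by construction. Regions that followed AsiDNA on both backgrounds were 2260 gained and 1634 lost, or 2.12% of all regions, which is 0.997 times the split of neither drug (interval 0.954 to 1.04). They were also close to the number that independent comparisons over all 183659 regions would share, 2156 gains and 1747 losses. Only 89327 regions were not in every list and could differ. Counting only these would raise the expected numbers, so the closeness depends on that choice. With stronger peaks only (−log10 q of 5 or more in every list) the ratio was 1.09 (interval 1.03 to 1.15). At gene ends the AsiDNA split held 97 genes against 80 in the split of neither drug, a ratio of 1.21 (interval 0.90 to 1.63). When a gene end had to have a peak at −log10 q of 5 or more to be present and no peak at all to be absent, the counts were 38 and 19 and the ratio 2.00 (interval 1.16 to 3.45). With a window of 2000 bp the counts were 114 and 114 (interval of the ratio 0.77 to 1.3), by merged regions 86 and 78 (0.81 to 1.5), and with lists of equal length 87 and 75 (0.85 to 1.58). The size of an AsiDNA effect that holds on both backgrounds is thus not settled by these lists.

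Gene ends open in both AsiDNA lists only belonged to 54 genes and those open only without AsiDNA to 43, against 55 and 25 genes on the sides of the split of neither drug. After ATP2A1 and ADAMTS8, whose merged regions also held peaks of the other lists, the named gained genes were RNF212B (folds 6.03 with AsiDNA and 5.58 with the combination), LOC107983987, URI1, a prefoldin-like chaperone (4.66 and 5.40), OR6J1, SPDYE2, MYOD1, the myogenic transcription factor (4.44 and 5.08, chromosome 11, 17722077 to 17722421), and TNFAIP8L2 with its read-through TNFAIP8L2-SCNM1 (5.84 and 4.62). RNF212B, OR6J1 and TNFAIP8L2-SCNM1 lost the pattern at 2000 bp. Open without AsiDNA only were DEFB132, a beta-defensin (5.44 in vehicle and 6.03 in belinostat), VIP, which encodes a neuropeptide (4.97 and 4.87), OR5P3 (5.68 and 4.87), LOC107987432, USP17L15, CDH12, a cadherin (4.02 and 5.10), SMIM36 and SULT1C2, with DEFB132 and SMIM36 losing the pattern at 500 bp. GPRC5D and RAD51AP2, also named, had peaks of other lists in the same merged region. Among genes that kept their pattern by merged regions, the lowest within-list percentile reached at most 41.99 (RNF212B, gained) and 45.62 (DEFB132, lost). Ranked the same way, it reached 40.55 (GADD45G, single-drug lists) and 36.99 (DYSF, vehicle and combination) in the split of neither drug. Peak strength thus does not set the top AsiDNA genes apart from that reference. The strongest distal gain, at 57966814 to 57967116 on chromosome 6, had folds of 8.03 and 8.22, and the strongest distal loss, at 95087428 to 95087768 on the same chromosome, 7.09 and 9.50.

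The combination list shared more peaks with the belinostat list than with the AsiDNA list: 12.5% of its peaks had no belinostat counterpart and 18.4% no AsiDNA counterpart. Of 32795 regions gained with belinostat over vehicle, 54.6% (interval 54.0 to 55.1) were also in the combination, and of 24149 lost with belinostat 74.4% (73.8 to 74.9) were also absent from it. The shares for AsiDNA were 37.4% (36.8 to 38.1) of 23994 gained and 66.5% (65.8 to 67.3) of 15532 lost regions. All 4 shares use the vehicle list on both sides, so part of each overlap can come from that list, and no value for lists without a drug effect is at hand. Against vehicle the combination gained 28670 peaks (21.3%, 21 to 21.5) and lost 24290 (18.6%, 18.4 to 18.9), fewer than belinostat alone in both directions.

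Regions specific to the combination were 8055 present in it alone and 4130 absent from it alone. The single-list counts for the other groups were 8701 for vehicle, 12343 for belinostat and 12461 for AsiDNA, so the combination had the fewest regions of its own. Regions absent from 1 list alone were 6723 for vehicle, 4837 for belinostat and 3843 for AsiDNA. The strongest combination-only region away from gene ends was in ATP9B (fold 12.2, chromosome 18, 79200700 to 79200897), followed by 1 in TICRR, a replication initiation factor (9.46, chromosome 15, 89614231 to 89614502), and 1 in OSBPL10 (8.14). Missing from the combination alone were, among others, regions in ANKRD17 (73208473 to 73208988 on chromosome 4, folds 7.33, 8.34 and 8.17 in vehicle, belinostat and AsiDNA) and NACC2 (9.82, 7.57 and 11.3).

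At gene ends 121 genes had a peak in the combination list alone, against 130 in vehicle, 236 in belinostat and 206 in AsiDNA alone. Of the 10 named by rank, 9 lay at the border of a peak that other lists also held (MAMDC4, BHMT, GDF10, CA14, MARCO, MARCKSL1, SORL1, PRAMEF7 and KRT79), which leaves LOC105377864 (fold 5.77). Ranked by merged regions, the next were TMPRSS11E (5.54), CASKIN1, CHRNA1, the muscle acetylcholine receptor subunit, LGALS13 (each 5.31) and CDC14A, a cell-cycle phosphatase (5.22). TMPRSS11E and CASKIN1 lost the pattern at 500 bp and CHRNA1 at 2000 bp. A peak was missing from the combination alone at 116 genes, against 190 for vehicle, 100 for belinostat and 85 for AsiDNA, so the number is not unusual. IFI44 (folds 6.97, 8.11 and 9.11) and GBP1 (5.20, 5.10 and 4.90), both induced by interferons, KIR3DL1 (5.93, 5.94 and 7.21), PLSCR2, ADGRB3 and FGL1 kept this pattern over the merged region, while TDRD12, OVOL3, OTP and GPRC5C did not. IFI44, KIR3DL1 and PLSCR2 lost it at 2000 bp, and GBP1, ADGRB3 and FGL1 kept it with both other windows.

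Most genes of DNA repair and of histone acetylation had open ends in every condition. A gene-end peak in all 4 lists was found at 22 of 24 genes of homologous recombination and the Fanconi pathway, 16 of 17 of non-homologous end joining, 19 of 20 of base excision and single-strand break repair, 18 of 18 of damage checkpoint signalling, 17 of 18 histone deacetylases, sirtuins included, and 19 of 19 histone acetyltransferases and bromodomain readers. Each count lay at percentile 99.7 or above among 10000 random gene lists of the same size. SIRT2 (folds 10.5 in vehicle, 14.3 in belinostat, 11.2 in AsiDNA and 14.5 in the combination), KAT2A and TAF1 were the highest-ranked members of the 2 chromatin lists together with SIRT3. MRE11, MAD2L2 and NEIL1 had a gene-end peak in no list, but 5, 6 and 1 regions lay inside or within 10 kb of them. A peak at a start inside the gene would not be counted as a gene-end peak. In these 6 lists the members that differed between conditions were RBBP8, which starts DNA end resection, with peaks in both belinostat lists (folds 7.88 and 9.0) beside an AsiDNA peak in the same merged region, and HDAC9, with weak peaks in both AsiDNA lists (3.5 and 3.0).

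Most genes of the housekeeping and response lists also had gene-end peaks in every condition. All 24 housekeeping genes, 21 of 22 apoptosis genes, 23 of 27 cell cycle genes, 19 of 22 p53 targets, 22 of 25 interferon and DNA sensing genes and 18 of 20 immediate early genes had peaks in every list. These counts lay between percentile 98.7 (p53 targets) and 100 (housekeeping genes) of random lists. High percentiles were thus not particular to repair or histone acetylation genes. The exceptions that fell into a named class were weak: TNFRSF10A, a death receptor, in all lists but the combination (3.55, 2.65 and 3.24), CCND2 in the combination list (3.03), AEN, a p53-induced exonuclease, in the single-drug lists, and EGR2 in vehicle and combination (2.17 and 2.94). AEN and EGR2 left their class when the window was narrowed to 500 bp or widened to 2000 bp, and CCND2 when it was widened.

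Gene-end peaks were common at astrocyte and glioma genes and less so at genes of other lineages. Of the astrocyte and glioma genes 19 of 24 were open in all lists (percentile 93.9), among them ALDH1L1 (folds 8.98 to 14.0) and FN1, fibronectin (7.34 to 11.7), while GFAP, AQP4, SLC1A2, SLC1A3 and PROM1 had no gene-end peak in any list. Counts were lower for neuronal (11 of 28, percentile 0.51), oligodendrocyte (5 of 14, percentile 1.75), microglia and blood (8 of 19, percentile 2.85), hepatocyte (5 of 18, percentile 0.09), germline (7 of 22, percentile 0.10) and endothelial genes (2 of 15), and 16 of 26 HOX genes were open in all lists. In the belinostat lists only were VGF, a neuropeptide precursor (2.65 and 2.80), and CDH5, the endothelial cadherin (4.47 and 4.05). MAEL, a germline piRNA factor (4.11 and 2.76), and HOXD9 (2.77 and 2.85) were in the lists without belinostat only. SYCP1 was in both AsiDNA lists only (3.04 and 3.69) and SYCP2 in all lists but the combination (4.08, 3.30 and 4.69), both being proteins of the synaptonemal complex. CDH5 left its class with either other window and VGF and MAEL with the wider, while HOXD9, SYCP1 and SYCP2 kept theirs. Germline, HOX and endothelial genes were the groups with most members in 1 to 3 lists, 5 of 22, 5 of 26 and 3 of 15, at percentiles 97.8, 95.8 and 91.9. The random lists did not keep neighbouring genes together. Members that share a peak, possible among HOX genes, are thus not allowed for.

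**Figure D3:**
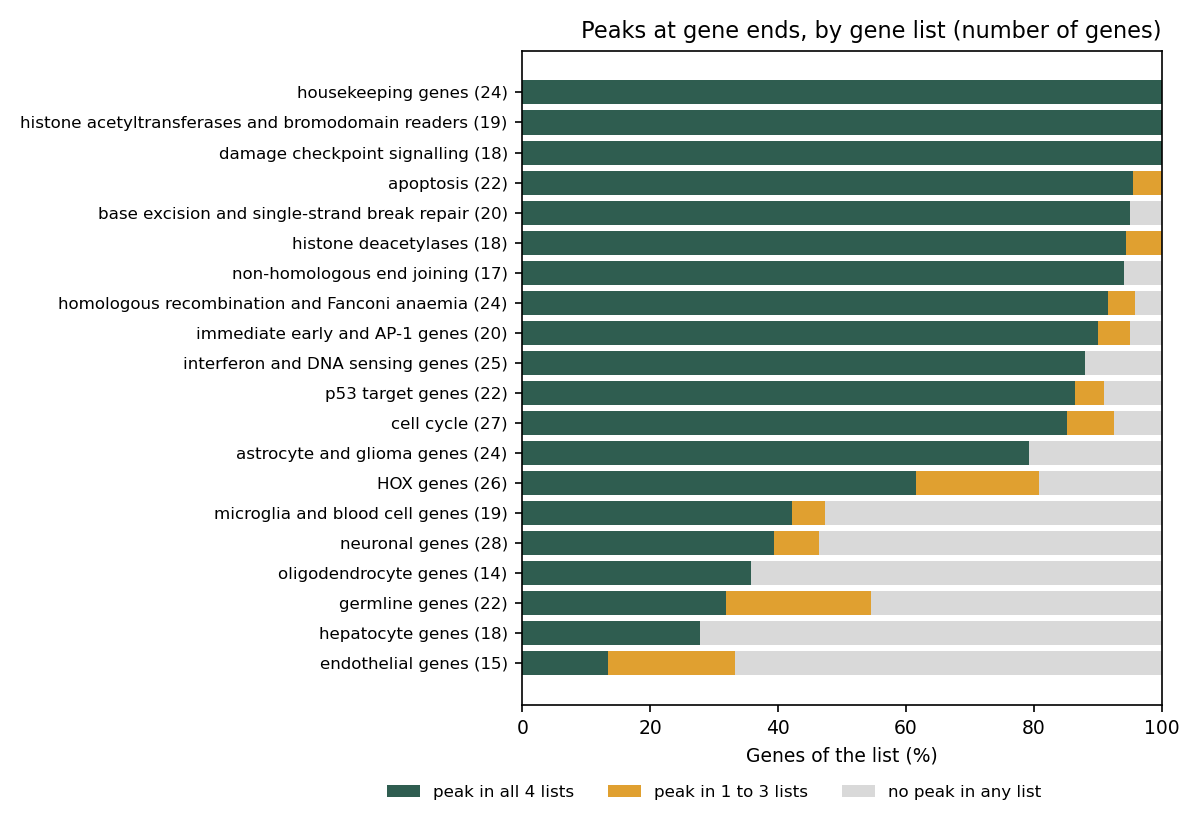
Share of the genes of each list (horizontal axis, percent; number of genes in brackets) with a peak within 1000 bp of a gene end in all 4 peak lists (green), in 1 to 3 of them (orange) or in none (grey). Repair, checkpoint, chromatin and housekeeping lists are nearly filled by genes open in every list, while endothelial, hepatocyte and germline genes are mostly not.

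Gene-end peaks were narrower in the lists with belinostat than in those without. In the 10666 gene-end regions with exactly 1 peak per list, median widths were 810 bp in vehicle, 755 bp in belinostat, 841 bp in AsiDNA and 743 bp in the combination. Belinostat peaks were narrower than vehicle peaks in 58.2% of these regions, and combination peaks narrower than AsiDNA peaks in 71.7%. Within these regions the median width ratio was 0.97 for belinostat over vehicle and 0.93 for the combination over AsiDNA. It was 1.03 for AsiDNA over vehicle and 0.99 for the combination over belinostat. The belinostat shift against vehicle was thus no larger than a shift between lists without belinostat. Away from gene ends, over 78915 regions, the medians were 438, 455, 462 and 444 bp and the shares 45.3% and 57.5%. Both belinostat comparisons narrowed together in 46.9% of gene-end regions (interval 45.9 to 47.8) and in 31.9% of the others (31.5 to 32.2). AsiDNA peaks were narrower than vehicle peaks in 38.9% of gene-end regions and 39.5% of the others, and combination peaks narrower than belinostat peaks in 55.2% and 54.2%. Widths were compared after the lists had been examined.

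**Figure D4:**
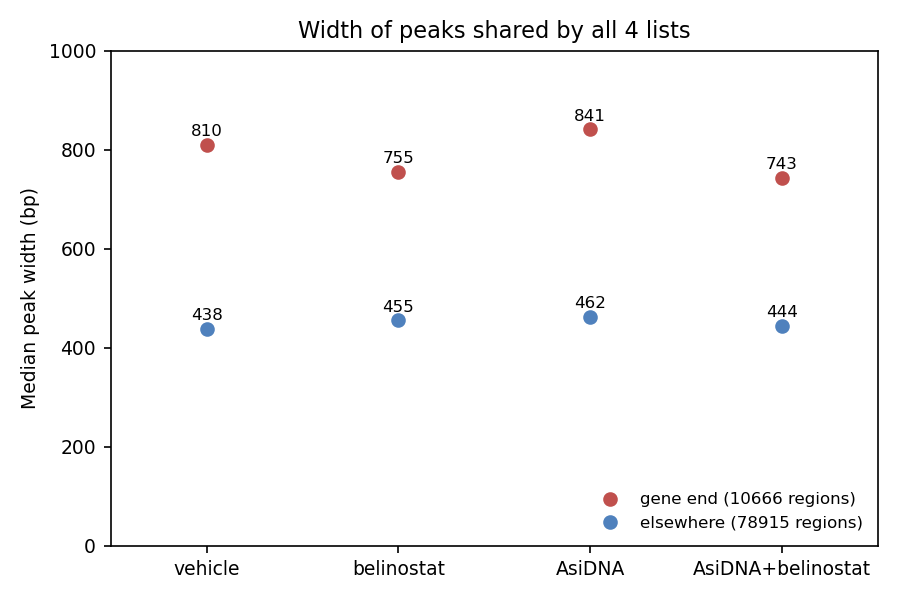
Median width of peaks in bp (vertical axis) in each of the 4 lists, over regions that hold exactly 1 peak of every list, at gene ends (red) and elsewhere (blue). At gene ends the belinostat lists have medians of 755 and 743 bp, below the 810 and 841 bp of the lists without belinostat.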

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

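The tests of peak strength, gain share, gene density and peak width in this part were chosen after the results were seen, except the width-matched test, whose prediction was written before it was run.

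The belinostat comparisons went in opposite directions without and with AsiDNA at 2550 regions, gained over vehicle but lost over AsiDNA. At 1354 regions they were lost over vehicle but gained over AsiDNA. These are the same regions as the 2 sides of the split of neither drug, which serves as the reference elsewhere. They cannot be told apart here from regions that differ between lists for no drug-related reason. The difference was not tested, since each group has 1 list. Independent comparisons of these sizes over all 183659 regions would share 5071 and 3212 such regions, so the counts are 0.50 and 0.42 times those numbers. Leaving out the regions in every list, which cannot change, would lower both ratios.

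The belinostat split held 5.23 times as many regions as the split that follows neither drug. Weak peaks that cross the calling threshold by chance would affect all splits alike, yet the ratio was 86.2 among regions at or above percentile 50 of their lists. More reads in the belinostat libraries would add peaks without removing others, yet 44.8% (interval 42.5 to 47.2) of those stronger regions were gains and the rest losses. Percentiles are ranked within each list, so the fold at percentile 50 differs between lists and can move this share. Without the filter the split held 11179 gains and 9257 losses. Better enrichment could both add and remove peaks, so the share of gains cannot decide on it. The deposited median fold enrichment was higher in the belinostat and combination lists (6.09 and 6.32) than in the vehicle and AsiDNA lists (5.75 and 5.87). These values are not scaled between lists, and as medians over all peaks they do not give the gap at gene ends. An effect of belinostat on accessibility is the candidate explanation that the design provides. With 1 list per group, a difference of the libraries that goes with belinostat for another reason, enrichment included, cannot be told apart from it.

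Belinostat-only regions lay in gene-dense sequence more than regions present only without belinostat, at 10.4 against 7.67 genes per Mb. A lean of the belinostat list by itself may contribute, because the split of neither drug, in which that list also sits on the gene-dense side, gave a ratio of 1.26 (interval 1.17 to 1.38). It cannot be the whole of it: the combination over AsiDNA, which does not use that list, gave 1.19 (interval 1.16 to 1.22). A bias of base composition shared by the belinostat libraries was not tested and stays open beside an effect of the drug.

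Gene-end peaks were narrower in the belinostat lists. If wide peaks narrowed wherever they lie, regions elsewhere weighted to the same widths would match the 46.9% of gene-end regions that narrowed in both comparisons, and their share was 36.1%, a difference of −10.8 points (interval −12.0 to −9.61). Fewer reads or a stricter threshold in the belinostat list would narrow most peaks, but 45.3% (interval 45.0 to 45.7) of those away from gene ends were narrower than in vehicle. For the combination against AsiDNA that share was 57.5% (interval 57.1 to 57.8), so a narrowing of all peaks cannot be told apart there from 1 specific to gene ends. Higher acetylation spreading or removing nucleosomes next to gene ends was not tested. A difference of enrichment between the lists was not tested for the widths either and stays open.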

How the results depend on the processing

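Merged-region presence, the stronger gene end and the percentile 50 filter were chosen after seeing the data; the other settings were planned. No paired analysis was possible because each group has 1 list, though the labels share replicate numbers, and leaving out a replicate was not possible for the same reason. The motif search and the 5-prime gene end were not run. Counts within 1.5 times of the main value were 51 of 60 for gained and lost peaks, 40 of 48 for regions and 46 of 56 for gene ends. The belinostat split stayed above the split of neither drug at every setting. For regions its ratio went from 5.23 to 7.45 with −log10 q of 5, 5.99 with equal lengths, 5.05 with 50% overlap, 4.98 by summits, 9.75 with a margin (present only at −log10 q of 5, absent only with no peak) and 86.2 at percentile 50. For gene ends it went from 4.14 to 3.21 with a 2000 bp window and 9.95 with the margin. The AsiDNA ratio went from 0.997 to 1.09 with −log10 q of 5, 1.1 with the margin and 1.20 at percentile 50 (interval 0.67 to 2.15), and for gene ends from 1.21 to 2.00 with the margin (interval 1.16 to 3.45). The causes were not tested.

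The margin leaves out weak peaks by construction and lowered most counts. Gained peaks fell to 13668 for AsiDNA over vehicle, 16524 for the combination over AsiDNA and 9471 over belinostat. Lost peaks fell to 6908 for AsiDNA over vehicle, 15063 for belinostat over vehicle, and for the combination to 18605 over AsiDNA, 10883 over belinostat and 14390 over vehicle. Regions fell to 1008 in both AsiDNA lists only, 571 in the lists without AsiDNA, 978 in the single-drug lists, 458 in vehicle and combination, 3584 in the combination alone and 2136 in all lists but it. Gene ends in the same order fell to 25, 13, 15, 4, 62 and 43, and to 107 and 82 with and without belinostat. With −log10 q of 5 in every list, AsiDNA over vehicle lost 9941 peaks, 1038 regions were in the lists without AsiDNA only and 855 in vehicle and combination, with 12 gene ends; a 2000 bp window gave 44 gene ends there. The share of peaks at gene ends over all lists was 10.2%, 10.9% with −log10 q of 5 and 10.5% at equal lengths.

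Named genes depended on the window. Of 10 per pattern, those that kept their pattern by merged regions, at 500 bp and at 2000 bp were 7, 4 and 4 for belinostat only, 3, 2 and 3 without belinostat, 8, 8 and 5 for AsiDNA only, 8, 6 and 8 without AsiDNA, 1, 1 and 1 for the combination alone and 6, 6 and 3 for all but the combination. All kept it at a −log10 q of 5, which says little. These genes were picked for their stronger peaks, and a higher threshold cannot add a peak to a list without one. Depth limits calls near the threshold, and gained and lost peaks were weak as a group.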

Other observations

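The regions within 10 kb of listed genes and the stretches without peaks were examined after the data were seen, and no explanation was tested for them.

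Large genes differed in which belinostat pattern filled them. NHS, on X, had 10 belinostat-only regions and 0 of the opposite kind among 60 regions in its neighbourhood, GPHN, the inhibitory synapse scaffold gephyrin, had 10 and 1 among 83, and SYN3, a synapsin, 9 and 1 among 75. CDH13 had 11 and 3, and SRGAP2 8 and 0. The reverse held at NRG1, the ligand neuregulin, with 1 belinostat-only and 13 without-belinostat-only regions among 100, PDE4D with 1 and 12 among 122, MAPK10, a neuronal kinase of the JNK family, with 1 and 10 among 37, PARD3 with 1 and 9, and PCDH9, a protocadherin, with 0 and 8. These genes are the extremes of all 19974, so their counts are selected to be large.

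Within 10 kb of the fixed gene lists, astrocyte and glioma genes had 25 belinostat-only and 20 without-belinostat-only regions, at percentiles 99.2 and 98.2 of length-matched random lists, but they also had more regions of any kind (329, percentile 99.3). EGFR had 5 of the former and 0 of the latter, and PROM1, which encodes the stem cell marker prominin, 0 and 5. Neuronal genes had 21 and 9 (difference at percentile 94.4), with 4 and 0 at SNAP25 and 3 and 0 at CELF4. Housekeeping genes had 9 and 1 (difference at percentile 95.6). Genes of homologous recombination had 4 and 11, the former at percentile 0.84, among few regions of any kind (133, percentile 0.51). With 20 lists examined, values of this size at either end are not rare.

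No list held a peak on chromosome 9 between 20034046 and 23581861, a stretch of 3.55 Mb with 24 protein-coding genes, 16 of them interferon genes beside CDKN2A, CDKN2B and MTAP. U87 is a line described as lacking CDKN2A. Of 145 such stretches of at least 400 kb that contain protein-coding genes (459 genes in all), 7 lay on chromosome 19, otherwise rich in peaks, and 69 of their 78 genes were zinc finger genes by name, with 17 of 18 in the stretch from 21397311 to 23914644. Olfactory receptor genes filled another on chromosome 11 (54418042 to 56624599), with 43 of 45 genes.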
